A study of Mus musculus with 4 samples.

How the data were processed

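RNA from mouse astrocytes treated with NC siRNA or with Ptbp1 siRNA was analysed, with 2 libraries per group. Per the labels' protocols, total RNA was isolated with an RNeasy kit and libraries were built with a SMARTer kit for mRNA sequencing. The labels do not say what NC stands for, and the columns of the deposited table name that group as the control. Per the submitters' processing notes, the genome builds are GRCm38 and mm10, which name the same mouse assembly. The aligner, the counting tool, its strand setting, the annotation release and the statistical test behind the deposited comparison are not given in the sources used here.

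The authors deposited a table of 54532 genes with whole-number counts per gene and library, not normalized. The deposited FPKM values (fragments scaled to gene length and library size) use a library size that equals the median-ratio size factor times the geometric mean of the library totals, as recomputed from counts, lengths and FPKM, so they already carry a between-library scaling. The deposited group means are a signal of size-factor-scaled counts averaged over the 2 libraries of a group. The authors also deposited a log2 fold change, a p-value and an adjusted p-value for Ptbp1 siRNA over NC siRNA, and 26980 genes have such a p-value, which are those with a count total of at least 2 over the libraries. Gene symbols, biotypes and coordinates were taken from the same table, whose coordinates are on GRCm38.

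The counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalization, filterByExpr with its defaults, group as the only term). Of 29505 genes with a count, 16368 passed the filter. TMM factors lay between 0.997 and 1.003. A call is a Benjamini-Hochberg adjusted p under 0.05, two-sided. The model had 2 residual degrees of freedom and a prior of 14.0 degrees of freedom from the other genes. Levels are CPM on the TMM-scaled library sizes, and standard errors and 95% intervals of log2 fold changes were derived from the quasi-F statistic. The share of counts in ribosomal RNA genes was 0.758% and 0.907% in the NC siRNA libraries and 0.695% and 1.06% in the Ptbp1 siRNA libraries, and the mitochondrial share was 0.868% to 0.907%. The labels mention no molecular identifiers, so counts can include PCR copies.

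Before the data were examined, the groups, the tests, the alternatives, 27 gene lists and the rule for named genes were fixed. Lists were tested with camera in limma 3.58.1 on the edgeR counts with the preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation and with fry. Matched symbols include 2 that the table gives under an older name, and a symbol with several identifiers was read as the one with the most counts. Ptbp1 is in none of the lists. The rule named Ptbp1, Ptbp2 and Ptbp3; the 8 largest positive and 8 largest negative fold changes among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 CPM, a symbol that is not a predicted-gene name and groups that do not overlap; and, per list, up to 3 members with the smallest adjusted p or, where none passed, the 2 members with the highest mean. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

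The edgeR and camera steps were tested on simulated counts drawn from the means, library sizes and trended dispersion of these libraries, with 200 genes changed in each of 5 simulations. A list of 25 genes lowered 1.2-fold was called in 5 of 5 simulations, and 0 of 135 unchanged lists were called. The simulated genes vary independently, so this says nothing of lists whose genes vary together between cultures. Reads shared between genes were gauged as the share of a gene's 50-base stretches that occur in transcripts of other genes in GENCODE M21, which is also on GRCm38 and holds 54336 of the gene identifiers. Genes with a share of at least 50% are called multi-copy.

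The alternatives were median-ratio (RLE) scaling, library size with no scaling factor, DESeq2 1.42.0, limma on log2(FPKM + 1), no filter on low counts, a mean of at least 1 CPM, an absolute log2 fold change of at least 1 as a second threshold, the replicate number as a block, and leaving out each library in turn. Each column of per-sample values was matched to a sample by the labels. With 2 libraries per group, no rule for outlying samples was applied.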

Results

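Gene expression was measured by RNA sequencing in mouse astrocytes, the glial cells that maintain ion, transmitter and nutrient balance around neurons. The cells received either a small interfering RNA (siRNA, a short duplex that directs the degradation of a matching transcript) against Ptbp1 or a control siRNA labelled NC. Each group had 2 libraries. The gene counts totalled 16009248 in NC siRNA 1, 15002578 in NC siRNA 2, 14557844 in Ptbp1 siRNA 1 and 14981622 in Ptbp1 siRNA 2, and between 24273 and 24780 genes had at least 1 count in a library. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The libraries of every pair differed by more than counting error alone gives when reads are taken as independent, a comparison that does not tell spread between cultures from spread in preparation or PCR copies. Over genes with a count total of at least 40, the chi-square per degree of freedom ran from 3.06 for NC siRNA 1 and Ptbp1 siRNA 1 to 6.16 for NC siRNA 1 and Ptbp1 siRNA 2. The biological coefficient of variation of the fitted model was 6.42%.

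The NC siRNA cultures held transcripts of astrocytes and of other cell types. The intermediate filament genes Vim and Gfap stood at 5923 ± 99.5 and 899 ± 35.9 normalised counts (CPM, scaled to the library size; mean ± SD, n = 2). Among the markers of other cells, Lyz2, the lysozyme of macrophages and microglia, stood at 668 ± 6.53 CPM, and Foxj1, the transcription factor of cells with motile cilia, at 331 ± 8.69 CPM. The oligodendrocyte lineage factor Olig1 was at 175 ± 4.32 CPM and the collagen gene Col3a1 at 1041 ± 55.8 CPM. Among neuronal genes, Map2 stood at 154 ± 10.96 CPM and Stmn2 at 83.6 ± 2.04 CPM. The genes named so far are among the highest of their lists. Over the tested members of a list, the median level with NC siRNA was 74.9 CPM for astrocyte markers. It was 77.9 CPM for fibroblast and pericyte markers and 39.1 CPM for microglia and macrophage markers. For oligodendrocyte lineage, neuronal and ependymal markers it was 8.62, 8.31 and 7.62 CPM. Counts of Rbfox3, which encodes the neuronal nuclear antigen NeuN, were 0 and 5 in the NC siRNA libraries and 1 and 4 in the Ptbp1 siRNA libraries, and those of the migrating-neuron gene Dcx were 3, 7, 5 and 10 in the same order. Rbfox3 and Dcx were chosen after their values were seen, and both lay below the count filter of the main test.

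The comparison of the siRNAs asked how astrocyte gene expression differs when Ptbp1 is lowered. Ptbp1 encodes polypyrimidine tract binding protein 1, a splicing repressor of non-neuronal cells. Ptbp1 (ENSMUSG00000006498; GRCm38 chromosome 10, 79854427 to 79864771, plus strand, protein coding) was partly reduced, from 298 ± 3.61 CPM with NC siRNA to 199 ± 5.13 CPM with Ptbp1 siRNA (mean ± SD, n = 2), which is 33.1% lower. The separate libraries stood at 300.4 and 295 CPM with NC siRNA and at 203 and 196 CPM with Ptbp1 siRNA, and the raw counts were 4816, 4428, 2944 and 2914. The log2 fold change was -0.58 with a standard error of 0.063 and a 95% interval of -0.71 to -0.45, and the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.00127, the smallest of the 16368 genes tested. On log2(FPKM + 1) values tested with limma the change was of similar size, -0.57, with an adjusted p of 0.485.

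The paralogs of Ptbp1 did not pass the test. Ptbp2, the neuron-enriched paralog whose transcript PTBP1 is known to destabilise through exon skipping (ENSMUSG00000028134; chromosome 3, 119718742 to 119784466, minus strand), stood at 57.0 ± 2.42 CPM with NC siRNA and 63.1 ± 1.02 CPM with Ptbp1 siRNA. Its log2 fold change of 0.14 (SE 0.077, 95% interval -0.02 to 0.31) corresponds to a fold between 0.988 and 1.24, with an edgeR adjusted p of 1.00. Ptbp3 (ENSMUSG00000028382; chromosome 4, 59471868 to 59549364, minus strand) stood at 92.6 ± 7.57 and 87.1 ± 0.218 CPM, a log2 fold change of -0.09 (SE 0.075).

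Beside Ptbp1, 3 genes passed an adjusted p of 0.05, so that 1 gene was higher and 3 were lower among the 16368 tested. Rsph3a, a radial spoke protein gene of motile cilia (ENSMUSG00000073471; chromosome 17, 7945614 to 7979824, plus strand), rose from 19.4 ± 2.50 to 37.2 ± 8.67 CPM, a log2 fold change of 0.93 (SE 0.14, edgeR adjusted p = 0.0272). The predicted gene Gm11361 (ENSMUSG00000113061; chromosome 13, 28257528 to 28258134, plus strand), named although its symbol lies outside the rule for named genes, fell from 23.3 ± 8.38 to 7.69 ± 0.911 CPM, a log2 fold change of -1.60 (SE 0.21, edgeR adjusted p = 0.00537). Both libraries of one group lay above both of the other for each of the 4 genes. That held for 31.5% of tested genes, where chance gives 33.3%. At an unadjusted p under 0.05 there were 652 genes, 3.98% of those tested. At that level DESeq2 gave 151 of 29505 genes, and the authors' deposited table held 151 of 26980.

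The sequences of these genes bear on how well their reads can be assigned. Of the 50-base stretches of the Gm11361 transcripts, 69.7% also occur in transcripts of other genes, among them the ribosomal protein gene Rps18 and the pseudogene Rps18-ps3, and its counts are therefore uncertain. For Rsph3a the share was 54.4%, held by its paralog Rsph3b, which stood at 15.9 ± 0.616 CPM with NC siRNA and 15.9 ± 0.246 CPM with Ptbp1 siRNA. The share was 4.75% for Ptbp1. Plppr3, on the opposite strand at the 3' end of Ptbp1, had 65 to 114 counts per library. Rsph3b and Plppr3 were chosen after their values were seen, and whether the counting used strand is not given in the sources used here.

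The number of calls moved with the libraries and the filter. It was 61 without NC siRNA 1, 75 without NC siRNA 2, 61 without Ptbp1 siRNA 1, 34 without Ptbp1 siRNA 2 and 50 with no filter on low counts, with the 4 genes among the calls each time. It was 0 with limma on log2(FPKM + 1), where 764 genes had an unadjusted p under 0.05. In the fits without a library and with no filter, the prior degrees of freedom became infinite. Each gene's spread there came from the trend over all genes, so their numbers of calls are not directly comparable with that of the main test. In the authors' deposited table, 26980 genes had a p-value and 4 had an adjusted p under 0.05, 3 lower and 1 higher, and the 4 were those called by edgeR. The authors' deposited table gave log2 fold changes of -0.58 for Ptbp1, 0.93 for Rsph3a and -1.60 for Gm11361, with adjusted p-values of 2.4e-11, 0.00601 and 1.8e-05. Data for this comparison were also simulated over 16368 genes. There, edgeR called 58.5% of genes changed 1.5-fold, 78.2% of genes changed 2-fold, 93.3% of genes changed 4-fold and 0.0496% of unchanged genes. The simulated genes took their spread from the trend over all genes, with no spread of their own. The shares of changed genes called may therefore be too high for the real libraries.

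**Figure D1:**
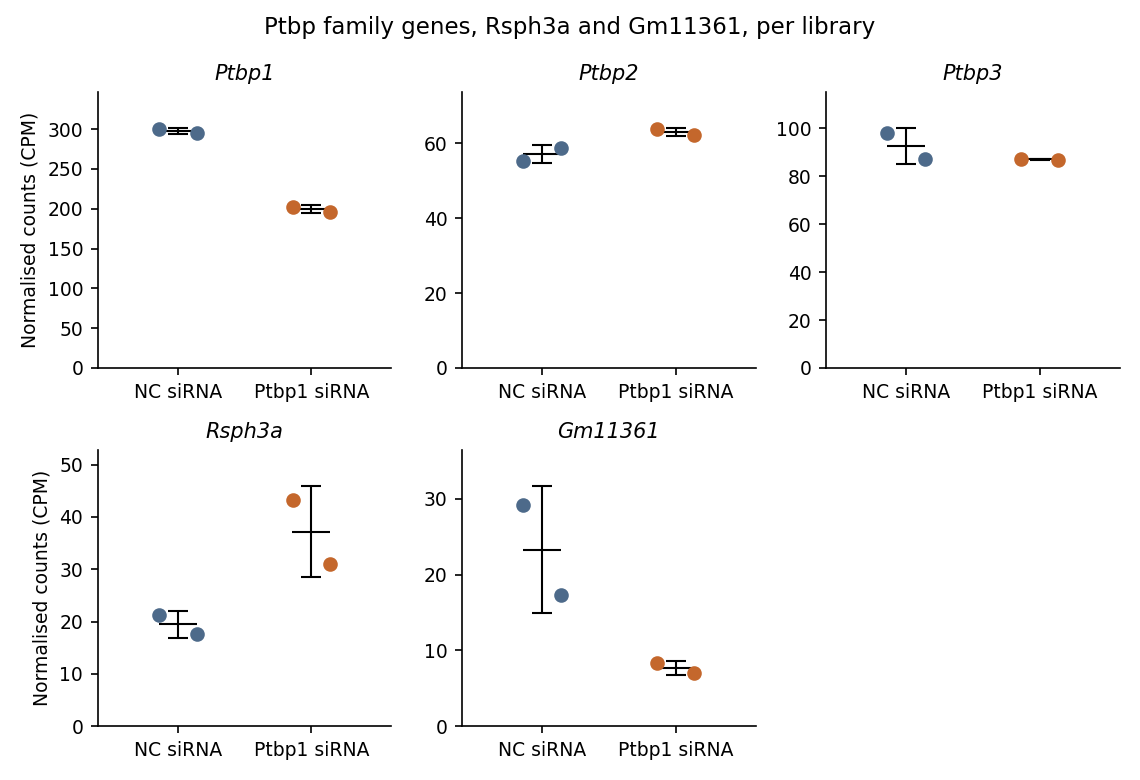
Normalised counts in CPM (y axis, from 0) of Ptbp1, Ptbp2, Ptbp3, Rsph3a and Gm11361 with NC siRNA and Ptbp1 siRNA (x axis). Each point is a library and the bars give the mean ± SD of 2 libraries. Ptbp1 stood at 300.4 and 295 CPM with NC siRNA and at 203 and 196 CPM with Ptbp1 siRNA. The log2 fold changes of Ptbp2 and Ptbp3 were 0.14 and -0.09 and did not pass the test.

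Gene lists fixed before the data were examined were compared between the groups with camera, which asks whether the members of a list stand higher or lower than the other tested genes. With the preset inter-gene correlation of 0.01, 5 of the 27 lists passed an adjusted p of 0.05, 4 lower and 1 higher with Ptbp1 siRNA. With an estimated correlation none passed: the smallest adjusted p was 0.903, and 0 lists had an unadjusted p under 0.05. The directional test of fry also called 0 lists, with a smallest adjusted p of 0.961 and 0 lists at an unadjusted p under 0.05. Both rest on 2 residual degrees of freedom, and the simulations tried only the preset correlation. Whether either could call a true shift of a list in these libraries was not tested. The number of lists called was 1 without NC siRNA 1, 5 without NC siRNA 2, 8 without Ptbp1 siRNA 1 and 0 without Ptbp1 siRNA 2.

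Markers of astrocytes stood lower as a group with Ptbp1 siRNA (camera adjusted p = 2.5e-05; adjusted p = 0.903 with an estimated correlation). The median log2 fold change of the 25 tested members was -0.08, and 21 of them had a negative value. Over all genes tested, 1 member passed. Adjusted over the list alone, 2 members were lower, among them Ndrg2, at 28.6 ± 3.34 CPM with NC siRNA and 20.98 ± 0.628 CPM with Ptbp1 siRNA (log2 fold change -0.45, SE 0.12, edgeR adjusted p = 1.00). Slc1a2, a glutamate transporter gene of astrocytes, stood at 41.6 ± 3.14 and 34.7 ± 2.23 CPM, with a log2 fold change of -0.26 (SE 0.095). Slc1a3, another such gene with higher counts here, stood at 188 ± 3.24 and 178 ± 11.3 CPM, with one of -0.08 (SE 0.068). Gfap stood at 899 ± 35.9 and 842 ± 105 CPM, with one of -0.09 (SE 0.075). Ndrg2, Slc1a2 and Slc1a3 were chosen after their values were seen. The call of the list was lost without NC siRNA 1 (adjusted p = 0.224) and without Ptbp1 siRNA 2 (adjusted p = 0.944, with the opposite direction).

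Lists of reactive astrocyte genes were not called, and none of their members passed over all genes or adjusted over the list alone. The median log2 fold change was 0.03 over 13 pan-reactive genes (camera adjusted p = 0.826), -0.02 over 12 genes of the A1 state described after inflammation (adjusted p = 0.947) and -0.04 over 11 genes of the A2 state described after ischaemia (adjusted p = 0.826). Vim stood at 5923 ± 99.5 CPM with NC siRNA and 6030 ± 7.62 CPM with Ptbp1 siRNA. The A1 genes H2-D1 and Gbp2 had log2 fold changes of 0.06 (SE 0.082) and -0.01 (SE 0.076), and the A2 genes S100a10 and Emp1 had -0.01 (SE 0.069) and -0.07 (SE 0.066).

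No list of neuronal genes was called. Of 22 tested neuronal markers none passed over all genes or adjusted over the list alone, and their median log2 fold change was -0.01 (camera adjusted p = 0.803). Map2, a microtubule-associated protein gene, stood at 154 ± 10.96 and 159 ± 10.4 CPM, and Stmn2, a gene of growing axons, at 83.6 ± 2.04 and 82.9 ± 1.98 CPM. The neuronal tubulin gene Tubb3, chosen after its values were seen, was at 9.58 ± 0.134 and 8.88 ± 1.17 CPM, with a 95% interval of the log2 fold change of -0.48 to 0.27. None of 11 proneural transcription factors passed (median log2 fold change 0.001, camera adjusted p = 0.826), with Sox4 at 0.05 (SE 0.067) and Lhx2 at 0.01 (SE 0.080). None of 12 members of the REST complex, a repressor of neuronal genes, passed either (median 0.001, camera adjusted p = 0.803), with Ctdsp2 at -0.05 (SE 0.065) and Hdac2 at 0.01 (SE 0.067).

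Genes connected with alternative splicing gave a similar picture at the level of whole-gene counts, which do not measure exon use. Of 15 neuron-enriched splicing regulators none passed over all genes or adjusted over the list alone (median log2 fold change 0.06, camera adjusted p = 0.615). Mbnl2 stood at 307 ± 7.61 and 320.0 ± 3.76 CPM, and Rbfox2 at 253 ± 0.111 and 264 ± 4.29 CPM. Of 20 genes with exons that the literature describes as controlled by PTBP1, none passed (median -0.001, camera adjusted p = 0.763). The filamin gene Flna stood at 1720.3 ± 167 and 1737 ± 177 CPM, and the tropomyosin gene Tpm1 at 1276 ± 21.4 and 1301 ± 50.6 CPM. Dlg4, the gene of the postsynaptic protein PSD-95, chosen after its values were seen, had a log2 fold change of 0.13 (SE 0.071, edgeR adjusted p = 1.00).

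Genes of the extracellular matrix and glial scar stood lower as a group with Ptbp1 siRNA (camera adjusted p = 2.5e-05; adjusted p = 0.903 with an estimated correlation of 0.91 between members). Their median log2 fold change was -0.12 over 32 members, 25 of them with a negative value, and no member passed over all genes or adjusted over the list alone. Fn1 stood at 1903 ± 334 and 1828 ± 310 CPM, and Sparc at 1477 ± 56.6 and 1418 ± 176 CPM. The markers of fibroblasts and pericytes, 4 of which are also in another list, were called lower too (median -0.12 over 17 members, 14 of them negative, camera adjusted p = 0.000138, and adjusted p = 0.903 with an estimated correlation). Adjusted over the list alone, 2 of these members were lower, the type I collagen genes Col1a1 and Col1a2, which were chosen after their values were seen. Col1a1 stood at 666 ± 83.8 and 521 ± 81.2 CPM (log2 fold change -0.35, SE 0.094) and Col1a2 at 675 ± 37.0 and 568 ± 64.4 CPM (log2 fold change -0.25, SE 0.075), each with an edgeR adjusted p of 1.00. Acta2, the smooth muscle actin gene, had a log2 fold change of 0.05 (SE 0.069) and Col3a1 one of -0.14 (SE 0.076). Without NC siRNA 1 the adjusted p was 0.469 for the matrix list and 0.224 for the fibroblast and pericyte list. Without Ptbp1 siRNA 2 these values were 0.521, with the opposite direction, and 0.944.

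The interferon and cytokine lists were called in opposite directions. Interferon-stimulated genes stood lower as a group with Ptbp1 siRNA (median log2 fold change -0.06 over 26 members, 18 of them negative, camera adjusted p = 0.00158, and adjusted p = 0.903 with an estimated correlation). None of them passed over all genes. Adjusted over the list alone, 1 member was lower, the antiviral gene Rsad2, chosen after its values were seen, at 267 ± 26.6 and 217 ± 2.13 CPM (log2 fold change -0.30, SE 0.072, edgeR adjusted p = 0.938). Ifit3 and Ifit1, the members with the highest counts, had log2 fold changes of -0.05 (SE 0.075) and -0.08 (SE 0.073). The call was lost without NC siRNA 2 (adjusted p = 0.344, with the opposite direction), without Ptbp1 siRNA 1 (0.0552) and without Ptbp1 siRNA 2 (0.119). Targets of NF-kB and cytokine genes stood higher as a group (median 0.12 over 23 members, 18 of them positive, camera adjusted p = 0.000839, and adjusted p = 0.903 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Csf1, a growth factor of macrophages, stood at 1492 ± 42.7 and 1626 ± 2.39 CPM (log2 fold change 0.12, SE 0.059), and the adhesion gene Vcam1 at 565 ± 76.5 and 588 ± 49.4 CPM. This call was lost without NC siRNA 1 (adjusted p = 0.835) and without Ptbp1 siRNA 2 (adjusted p = 0.629).

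Markers of the remaining cell types were not called, and no member passed over all genes or adjusted over the list alone. The median log2 fold change was -0.03 over 22 markers of microglia and macrophages (camera adjusted p = 0.217), with Lyz2 at -0.02 (SE 0.060) and the protease gene Ctss at 0.05 (SE 0.076). It was -0.07 over 14 oligodendrocyte lineage markers (adjusted p = 0.138), with Olig1 at -0.08 (SE 0.067) and Olig2 at 0.03 (SE 0.072). Over 11 endothelial markers it was -0.04 (adjusted p = 0.493), with Slco1a4 at -0.06 (SE 0.0996) and Cdh5 at -0.04 (SE 0.11). Over 12 ependymal markers it was -0.10 (adjusted p = 0.157), with Foxj1 at -0.09 (SE 0.062) and Cfap126 at 0.02 (SE 0.14). NC siRNA 2 stood apart from the other libraries in genes of the choroid plexus, which were chosen after their values were seen. Ttr, the transthyretin gene, was at 348 CPM in NC siRNA 2 and at 52.3, 38.8 and 52.3 CPM in NC siRNA 1, Ptbp1 siRNA 1 and Ptbp1 siRNA 2. Enpp2 was at 54.5 CPM there and at 10.3, 6.89 and 10.3 CPM in the other libraries in the same order. Neither gene passed the test between the groups, with edgeR adjusted p-values of 0.792 and 1.00.

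Genes of the cell cycle, of metabolism and of stress responses were not called, and none of their members passed over all genes or adjusted over the list alone. The 26 mitosis genes had a median log2 fold change of -0.06 (camera adjusted p = 0.0811), with Top2a at -0.05 (SE 0.080) and Mki67 at 0.04 (SE 0.13). The 24 DNA replication genes had a median of -0.03 (adjusted p = 0.763), with Pcna at 0.05 (SE 0.066) and Mcm7 at 0.14 (SE 0.067). Targets of p53 (22 genes, median 0.03, adjusted p = 0.761) included Cdkn1a at 1385 ± 80.8 and 1397 ± 83.7 CPM and Ccng1 at 1087 ± 41.7 and 1099 ± 35.8 CPM. The median was 0.01 for 20 glycolysis genes (adjusted p = 0.826), with Eno1 at 0.06 (SE 0.061) and Pkm at 0.01 (SE 0.060). It was -0.03 for 20 genes of cholesterol synthesis (adjusted p = 0.539), with Srebf2 at 0.02 (SE 0.070). For 12 mitochondrially encoded genes it was -0.02 (adjusted p = 0.359), with mt-Co1 and mt-Cytb at 0.01 (SE 0.058) and -0.01 (SE 0.059). Actin cytoskeleton and focal adhesion genes (24 genes, median 0.01, adjusted p = 0.947) included Actb at -0.02 (SE 0.059). Genes of the unfolded protein and integrated stress responses (21 genes, median 0.01, adjusted p = 0.718) included Atf4 at 0.08 (SE 0.067) and Hspa5 at 0.06 (SE 0.061). Autophagy and lysosome genes (24 genes, median -0.01, adjusted p = 0.803) included Ctsb at -0.02 (SE 0.063) and Ctsd at -0.03 (SE 0.063). Immediate early genes (18 genes, median -0.01, adjusted p = 0.826) included Jun at -0.02 (SE 0.062) and Junb at 0.05 (SE 0.079). The sign of the median differed from that of the mean or of the camera test in 5 of the lists not called, those of pan-reactive genes, A1 genes, proneural factors, the REST complex and genes with PTBP1-controlled exons.

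**Figure D2:**
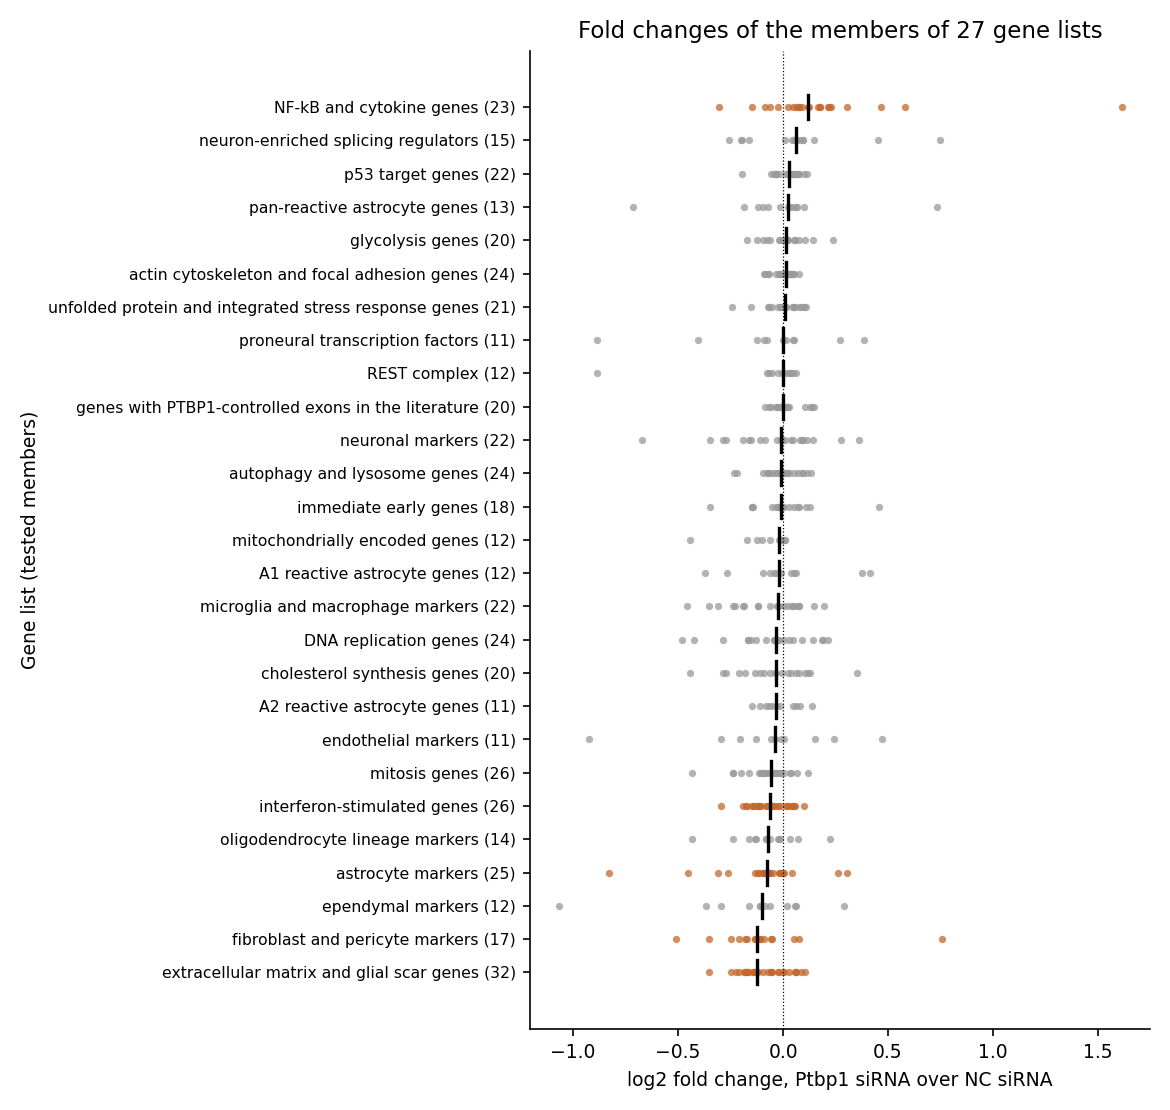
Log2 fold changes of Ptbp1 siRNA over NC siRNA (x axis) for the tested members of 27 gene lists (y axis, number of tested members in brackets). Each dot is a gene, the black bar is the median of the list and orange marks the 5 lists called by camera with the preset correlation. The medians run from -0.12 for the matrix and glial scar list to 0.12 for the NF-kB and cytokine list.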

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

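The alternatives were chosen before the data were examined. With RLE scaling, library size alone, DESeq2 or a mean of at least 1 CPM, 4 genes were called, the same 4 as in the main test. Limma on log2(FPKM + 1) called 0 genes, 0 higher and 0 lower, with 764 at an unadjusted p under 0.05, and gave Ptbp1 a log2 fold change of -0.57 that did not pass; the cause was not tested. A threshold of 1 on the absolute log2 fold change as well left 1 gene, 0 higher and 1 lower, by construction. With no filter, 50 genes were called, 18 higher and 32 lower. Leaving out a library gave 34 to 75 genes, 13 to 33 higher and 21 to 43 lower, and 0 to 8 lists. The 4 genes were among the calls each time, and Ptbp1 lay between -0.61 and -0.55. These fits keep 1 residual degree of freedom and assume that the lone library varies like the other group. In them, and with no filter, the prior degrees of freedom became infinite, so that each gene's spread came from the trend over all genes.

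The siRNA groups share replicate numbers, and nothing in the labels says that a number marks a shared culture or day. Deviations from the group means correlated at 0.0909 between libraries of the same number over 16368 genes and at 0.198 over the 10892 genes with a mean log2 CPM above 3. The chi-square per degree of freedom was lowest for the pairs of libraries of the same number, 3.06 and 3.88, against 4.36 to 6.16 for the other pairs. With the replicate block, 36 genes were called, 12 higher and 24 lower, among them the 4, and the number of lists stayed at 5 with the preset correlation, while with an estimated correlation the smallest adjusted p of a list was 0.946. Of the other genes named in the text, the block called Col1a1 (adjusted p = 3.7e-06), Col1a2 (0.00446), Eln (0.00049), Ndrg2 (0.0440), Rsad2 (0.00256), Sarnp (1.7e-05), Rps18-ps3 (0.000304) and the choroid plexus genes Ttr (1.5e-11), Enpp2 (1.0e-10) and Tmem72 (0.000435) lower, and Snrpe (7.6e-05) and Rps18 (0.0375) higher. This fit keeps 1 residual degree of freedom, with a prior of 61.0.

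An estimated correlation and fry each called 0 lists, with 0 at an unadjusted p under 0.05. Leaving out a library turned some directions, with the cause not tested. The adjusted p of the interferon list ran from 4.6e-12 to 0.344 and turned without NC siRNA 2. Those of the astrocyte list (1.9e-12 to 0.944) and the matrix list (8.4e-20 to 0.521) turned without Ptbp1 siRNA 2. The log2 fold change of Sumo2, which like Gm10241 was chosen after its values were seen, ran from -1.05 to 1.58 and was negative without NC siRNA 2 (-0.54) or Ptbp1 siRNA 1 (-1.05), and that of Gm10241 ran from -0.72 without Ptbp1 siRNA 2 to 1.14. Genes with few counts, such as Rbfox3 with 0 to 5 per library, were left out of the main test by its filter and entered the fits with no filter and with DESeq2, which covered 29505 genes.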

Other observations

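The further genes given here did not pass the test and were chosen after their values were seen. The elastin gene Eln stood at 144 ± 7.76 CPM with NC siRNA and 114 ± 11.6 CPM with Ptbp1 siRNA (mean ± SD, n = 2; log2 fold change -0.34, SE 0.078, edgeR adjusted p = 0.673). Snrpe, which encodes a core protein of spliceosomal small ribonucleoproteins, stood at 33.5 ± 4.62 and 47.8 ± 5.50 CPM (log2 fold change 0.51, SE 0.11, edgeR adjusted p = 0.393). Sarnp, whose product takes part in mRNA export, stood at 33.9 ± 6.80 and 19.8 ± 4.40 CPM (log2 fold change -0.77, SE 0.15, edgeR adjusted p = 0.197). The nuclear long noncoding RNA Malat1 was at 2515 and 2513 CPM in the NC siRNA libraries and at 2832 and 2894 CPM in the Ptbp1 siRNA libraries (log2 fold change 0.19, SE 0.058, edgeR adjusted p = 1.00). Sumo2, a small ubiquitin-like modifier gene, was at 68.8, 15.8, 74.2 and 20.5 CPM in NC siRNA 1, NC siRNA 2, Ptbp1 siRNA 1 and Ptbp1 siRNA 2, while the processed pseudogene Gm10241 was at 13.8, 40.8, 16.5 and 44.6 CPM in the same order.

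Of the tests that follow, those of near-identical copies and of multi-copy genes were chosen after the results were seen, as was the bootstrap interval used for the choroid plexus markers. The bounds for those markers and the test of the gene lists were set after the pattern was noticed and before the values they bear on were seen.

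Choroid plexus genes stood higher in NC siRNA 2 than in the other libraries, and were noticed from Ttr, Enpp2, Clic6 and Tmem72, the last at 11.1 CPM there and at 0.561 to 0.738 CPM elsewhere. In 23 further markers with at least 10 counts, none of them used to notice the pattern, the median log2 ratio of NC siRNA 2 to the mean of the other libraries was 0.48 (95% bootstrap interval 0.24 to 0.78), with 22 of 23 above 0, against medians of -0.12, -0.20 and -0.22 for the other libraries. Without NC siRNA 2, the median log2 fold change of these markers was -0.048 (interval -0.11 to 0.080). The value of -1 or lower required beforehand for an effect of the Ptbp1 siRNA was not reached. However, NC siRNA 2 itself stood only 0.48 above the other libraries in these markers. The pattern was also noticed as that library standing apart, so a small difference from NC siRNA 1 was likely from the start. This test therefore does not decide on an effect of the siRNA. Only 1 NC siRNA library remains in that comparison. The interval resamples markers, so it does not measure the spread between libraries. Choroid plexus cells in the NC siRNA 2 culture, a possible source, missed the median of 1 set beforehand as needed and lay under the 0.5 set as speaking against them, though by less than the interval, so this stays open. Of the 23 markers, 17 were at 1 CPM or more in each other library and 0 are in the lists of the report, and the labels name no sort that would remove such cells.

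Multi-copy genes were common among the leading genes of the comparison, 6 of the 20 with the smallest p against 4.63% of tested genes. They include Gm11361 and Rsph3a. Fisher's exact test gave a one-sided p of 0.000214, counting each gene as a separate draw. Gm11361 and Rps18-ps3, both among the 6, share sequence, and the pattern was noticed in these same genes. That p is therefore descriptive only. For Rsph3a, reads moved from its paralog Rsph3b are argued against, because the summed counts of both genes were still higher with Ptbp1 siRNA. The log2 fold change of the sum was 0.58 (95% interval 0.35 to 0.81, edgeR unadjusted p = 6.1e-05). The unadjusted p was the one required to be under 0.05. Adjusted over all genes, the edgeR p was 0.165, which is not a call. For Gm11361, of whose 50-base stretches 69.7% occur elsewhere, Rps18 and Rps18-ps3 together held 40.2 times its counts. Rps18 stood at 587 ± 93.6 CPM with NC siRNA and 682 ± 32.4 CPM with Ptbp1 siRNA, and Rps18-ps3 at 4.84 ± 2.51 and 1.09 ± 0.0201 CPM. The summed counts of Gm11361 and these copies had a log2 fold change of 0.17 (95% interval 0.000431 to 0.33, edgeR adjusted p = 1.00), the opposite direction to that of Gm11361. Because the copies make up most of that sum, it does not tell reads moved between the genes from a fall of Gm11361 itself, and this stays open. Copy-number or read-assignment differences between cultures, unrelated to the siRNA, also stay open as a cause. Splitting the libraries by replicate number put 2 multi-copy genes among the leading 20 (Fisher's exact p = 0.236, one-sided). The remaining split, which crosses siRNA and number, put 9 there (Fisher's exact p = 9.91e-08, one-sided), more than the 6 of the siRNA split. A high share of multi-copy genes among the leading genes is therefore not particular to the comparison of the siRNAs. An effect of the siRNA on these genes was not tested apart from this.

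The gene lists called with the preset correlation may reflect variation between cultures shared by the genes of a list. Splitting the same 4 libraries by replicate number called 14 lists with the same test, among them 5 of the 5 called between the siRNAs, and 60 genes against the 4 between the siRNAs, which points to a structure of the samples that follows the number. Each siRNA group holds 1 library of each number, so a difference that follows the number alone cancels between the siRNAs. The 14 calls thus show that list members vary together between libraries, not that the number gave the siRNA calls. With the number as a block, the same 5 lists were called at the preset correlation. The split that crosses siRNA and number called 2 lists, 1 of them among the 5, and 3 genes. With 3 splits in all, no share under 0.05 can be had. A change of these lists by the siRNA, on top of such variation, stays open. None of the 5 calls held with an estimated correlation (camera adjusted p = 0.903). That correlation rests on 2 residual degrees of freedom, so it does not decide the question. Each call was lost without at least 1 of the libraries.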
